A study of Arabidopsis thaliana with 8 samples.

How the data were processed

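Chromatin immunoprecipitation (ChIP) with an antibody against histone H3 dimethylated at lysine 4 (H3K4me2) was measured on a tiling array of chromosome 4 in whole seedlings of Arabidopsis thaliana Col-0, the reference accession of this plant. H3K4me2 is a histone mark found mostly over genes and little over silent, repeat-rich chromatin. Each of 4 replicates was hybridised on 2 arrays with the dyes exchanged, immunoprecipitated (IP) DNA in one channel and input DNA in the other, which gives 8 arrays of 1 group. The series title also names hybrids and the accessions C24 and Cvi. Samples of those were not analysed here.

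The deposited values are log ratios of the 2 channels, taken here as log2. Per the labels, the DNA was amplified and labelled directly with the dyes. The scanner settings, background correction, normalization and averaging are not given in the sources used here. The log base was inferred from the values: of the values under 0.01 in size, 96.3%, 92.6%, 91.9% and 88.3% in replicates 1 to 4 were whole multiples of the double-precision floating-point step of numbers between 8 and 16, a range that log2 intensities take. This does not exclude another base. The 2 arrays of each replicate held identical values in all 21800 rows, so the deposited table holds 1 value per dye swap, and n = 4 throughout. The values were not centred: the replicate medians were -0.96, -0.33, -0.71 and -0.38. Whether the ratio is IP over input or input over IP is not stated and was not settled, so tiles are described as above or below the median tile of the array, with no claim on which side the antibody enriched. The number of arrays limits the precision, and signal over background is unknown because intensities were not analysed here.

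Of the 21800 rows, 21761 were named by plate and well and 21285 of these held values in all 4 replicates. A further 476 were blank, as were the 39 rows with other names. The names give a plate set (TA, TB, TC, TD or PD), a plate number and a well of a 96-well plate. They give no gene and no position, and the gene table at hand holds no tile names. The planned comparisons of annotation classes, chromosome regions and gene lists, and the gene part of the naming rule, were therefore not run. The rule's fallback was used: the 2 highest and the 2 lowest tiles past the threshold with the same sign in every replicate, by tile name. The labels leave open how far the replicates are separate. The extract text ascribes the immunoprecipitated chromatin of replicates 2, 3 and 4 to 1 seedling batch, labelled II. The input chromatin carries a batch label of its own in each replicate, I to IV, so in replicates 3 and 4 the IP and input labels differ. The titles give replicates 1 and 2 a shared slide number, and 3 and 4 another. The p-values then measure only the spread between these samples, which may be technical.

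Each replicate was centred on its median. No loess or quantile normalization was applied, since many tiles of a ChIP array can carry signal. Each tile's mean was tested against 0, the median tile, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The pairs of replicates that share a slide number were compared with the same tool. Differences between plate sets were tested with the exact sign-flip permutation test over the 4 replicates, two-sided, in which at least 2 of the 16 sign patterns always reach the observed size. Correlations were computed across tiles, which are not independent replicates. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

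The limma step was tested on simulated data with the measured variances and 200 changed tiles among 21285. With independent replicates it recovered 48% of the tiles changed 2-fold and 13% of those changed 1.5-fold, with 4 false calls. With replicates 1 and 3, and 2 and 4, correlated at 0.70 as estimated from the data, it made 135 false calls. It then recovered 77 of the 100 tiles changed 2-fold and 52 of the 100 changed 1.5-fold. The higher recovery is no gain, because the spread between correlated replicates understates the error, which also raised the false calls. Recovery and the share of false calls depend on how many tiles are changed. In the data 17877 tiles were called, far more than the 200 simulated, so these shares do not carry over to the counts below.

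The alternatives fixed before the data were examined were values as deposited, centring on the mode, quantile normalization, replicates 2, 3 and 4 as 1 chromatin, the slide pair as a fixed or a random block, a change of at least 1.5-fold (limma treat), robust fitting with a trend, and each replicate left out in turn. Because the arrays of a swap are identical, a dye effect, single dye orientations and the 8 arrays as blocked units could not be computed, and a filter on tiles measured on all 8 arrays removes nothing. The summaries by plate set, plate and neighbouring well, and the other pairings of the replicates, were added after the data were seen. With replicates 2, 3 and 4 as 1 chromatin, limma used 1 variance for all tiles, so the spread of each tile did not enter. The correlation within random blocks was -0.79 for the slide pairs and -0.71 for replicates 1 and 4, and 2 and 3. A negative value shrinks the error, and the slide pairs gave more calls than the main fit, 9908 above and 9846 below. Fits on the averages of replicates 1 and 3, and of 2 and 4, were also tried and are not reported, because they average samples grouped by a measured outcome. A comparison of plate order with gene density was tried and is not reported, because the files name no genome build.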

Results

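H3K4me2 ChIP was measured against input DNA in 10-day-old Col-0 seedlings on a tiling array of chromosome 4, in 4 replicates of 1 group, each a dye swap deposited as a single log2 ratio per tile. The design has no second group, and the question it allows is which tiles differed from the median tile beyond the spread between replicates. The direction of the ratio is not stated, so above and below refer to the deposited sign. All values are centred on the replicate median unless said otherwise.

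The ratios covered a wide range in every replicate. The SD over the 21285 tiles was 1.42, 1.35, 1.48 and 1.34 in replicates 1 to 4, and the distributions had a longer tail on the low side, with a skewness between -0.65 and -0.37. Against the median tile, 8951 tiles were above and 8926 below at an adjusted p under 0.05 (limma, n = 4), and 3408 passed in neither direction. This split rests on the centring, since a median places as many tiles on either side. With the values as deposited, 4108 tiles were above 0 and 11245 below, so that 26.8% of the calls were above in place of 50.1%. Centred on the mode, the counts were 3592 and 13604, with 20.9% above. A difference of at least 1.5-fold was called for 5515 tiles above and 6094 below.

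**Figure D1:**
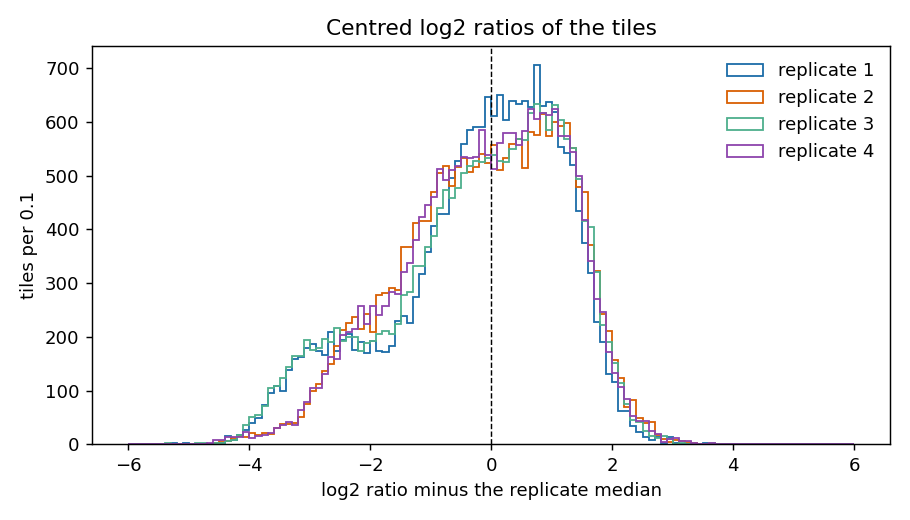
Number of tiles per 0.1 log2 units (y axis) against the log2 ratio minus the replicate median (x axis), 1 line per replicate; the dashed line marks the median tile. All 4 lines have a longer tail on the low side, with a skewness between -0.65 and -0.37.

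The highest tile, TA94E02, had a mean log2 ratio of 5.06 ± 0.26 (SD, n = 4), 33.4-fold from the median tile, with an adjusted p of 2.21e-06 in limma. Tile TA33E02 followed at 4.68 ± 0.19. At the low end, tile TA37C01 had -5.31 ± 0.17 and tile TC24D02 -4.69 ± 0.45. The rule that named these 4 tiles required the same sign in all 4 replicates. The files used here do not pair these names with genes.

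Tiles differed by plate set. The median log2 ratio was 0.48 ± 0.02 on the 100 TB plates, -0.50 ± 0.03 on the 99 TA plates and -0.75 ± 0.02 on the 27 TC plates (mean ± SD of the replicate medians, n = 4). As deposited, the TB median was -0.11, below 0. The 4 PD plates had -0.16 ± 0.02 and the TD plate 0.72 ± 0.03. TB plates exceeded TA plates by 0.98 ± 0.05 and TC plates by 1.24 ± 0.04, in 4 of 4 replicates each. TA plates exceeded TC plates by 0.25 ± 0.01. In the exact two-sided sign-flip test, 2 of the 16 sign patterns gave a difference as large in each of these 3 comparisons, the fewest possible with 4 replicates, so the test cannot reach 0.05. The TA and TC sets mix plates of unlike level: 30 of 99 TA and 13 of 27 TC plates were low as defined below. The TB set held 0 such plates. Plates TC00 to TC13 had medians from -0.475 to 0.914. The differences between sets are thus not a uniform shift of all plates.

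Within the TA and TC sets, most low plates lay next to each other. A plate median more than 1 below the array median in all 4 replicates was found for 43 of 231 plates, 30 of them TA and 13 TC, and for 0 of the 100 TB plates. The 10 plates TA21 to TA30 had a median of -2.06 ± 0.22 over 822 tiles. The 15 plates TA37 to TA51 had -2.18 ± 0.39 over 1339 tiles, and 95.5% of these tiles were below the median tile. The 13 plates from TC17 to TC30 had -2.24 ± 0.40 over 1098 tiles. Plates TA57 to TA59 were less low, at -1.41 ± 0.10 over 285 tiles, and plates TA53 and TA63 were low with no low plate beside them. The 188 other plates had a median of 0.30 ± 0.02.

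**Figure D2:**
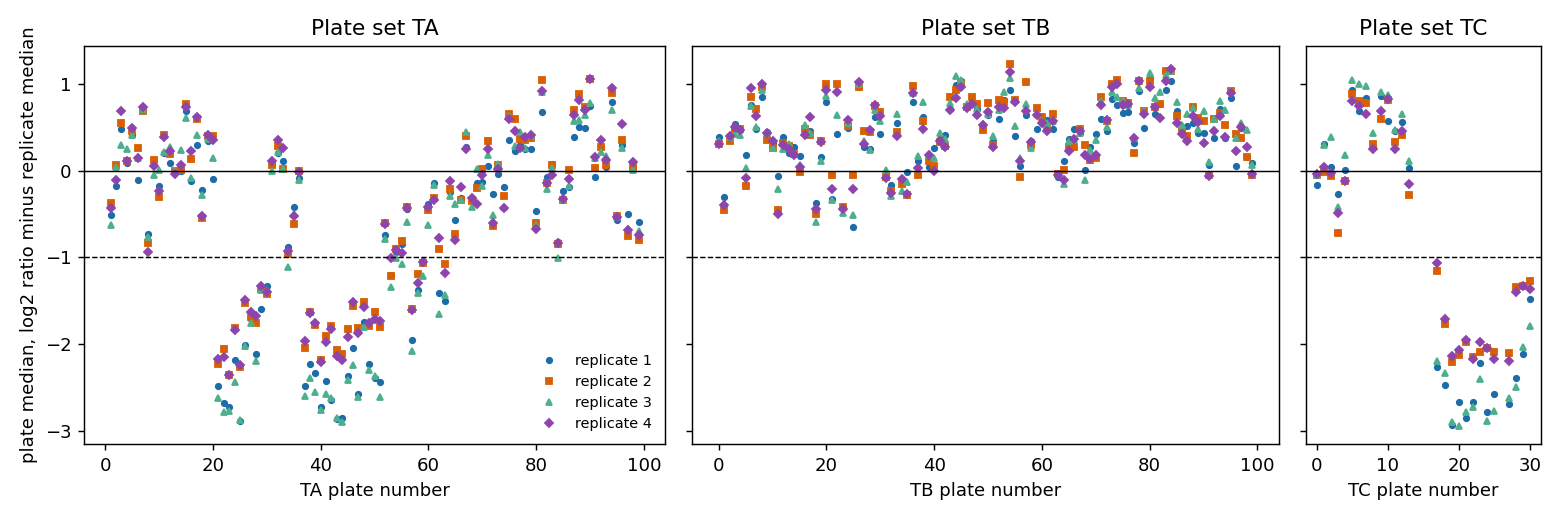
Median log2 ratio of each plate minus the replicate median (y axis) against the plate number (x axis) in the TA, TB and TC sets, 1 symbol per replicate; the dashed line lies 1 below the array median. Plates TA21 to TA30, TA37 to TA51 and TC17 to TC30 sit below it in all 4 replicates, and 0 TB plates do.

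Tiles in neighbouring wells had similar ratios. Counted along the plate rows, the correlation across tiles 1 well apart was 0.74 in TA, 0.61 in TB and 0.84 in TC. Counted down the columns it was 0.37, 0.11 and 0.68. Along the rows the correlation in TB fell to 0.25 at 3 wells and 0.01 at 96 wells. At 96 wells it was 0.27 in TA and 0.65 in TC, so much of the TC value is shared by tiles a whole plate apart.

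**Figure D3:**
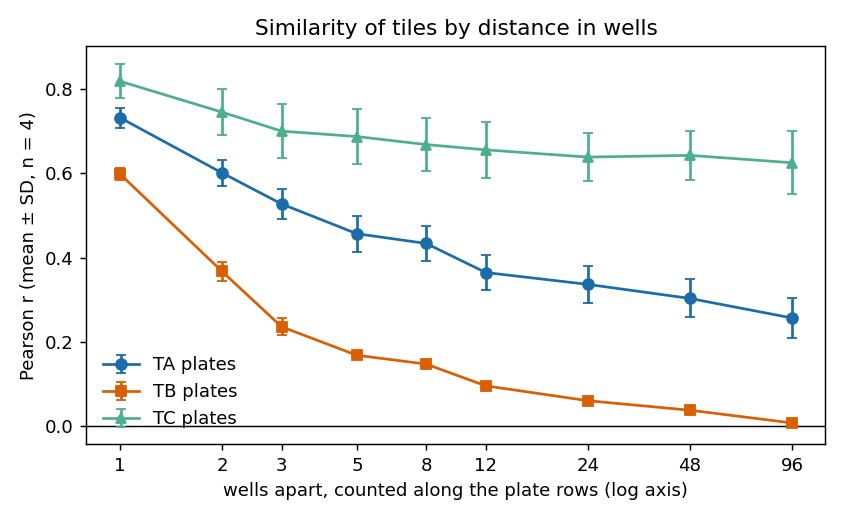
Pearson correlation across tiles (y axis; mean and SD bars of 4 replicates) against the distance in wells along the plate rows (x axis, log scale) for TA, TB and TC plates. The correlation in TB falls to about 0.01 at 96 wells, and TA and TC stay above it.

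The replicates were compared in pairs. The correlation across tiles was 0.985 for replicates 1 and 3 and 0.988 for replicates 2 and 4, and between 0.932 and 0.940 for the other 4 pairs. The SD of the difference was 0.26 and 0.21 for the first 2 pairs and between 0.50 and 0.52 for the others. The labelled batch, replicates 1 and 2 against 3 and 4 by slide number, gave 0 tiles at an adjusted p under 0.05 in limma and 28 at an unadjusted p under 0.05. Of the other 2 ways to split the replicates into pairs, 1 and 3 against 2 and 4 gave 7421 tiles, and 1 and 4 against 2 and 3 gave 0, with 38 at an unadjusted p under 0.05. The direction of the 7421 rests on the scaling: 2518 were higher in 1 and 3, against 3830 of 7554 after quantile normalization and 129 of 11830 as deposited. Without replicates 1, 2, 3 and 4 in turn the count was 7381, 3928, 7501 and 4239; each of these fits has an arm of 1 sample and takes its spread from the other pair. Chance alone would give about 1064 tiles at that unadjusted p, and in both comparisons with 0 calls the difference of 1 and 3 from 2 and 4 lies within each arm and enlarges the error, so these counts of 0 do not show that slide pairs were alike. The 4 replicates were therefore not independent in their deviations. With replicates 1 and 3, and 2 and 4, as random blocks (correlation 0.70), limma called 8177 tiles above and 8189 below the median tile. This pairing was chosen from the same values, and 2 blocks give little information on the spread between pairs. These counts therefore do not show how many calls would remain with 2 independent pairs.

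**Figure D4:**
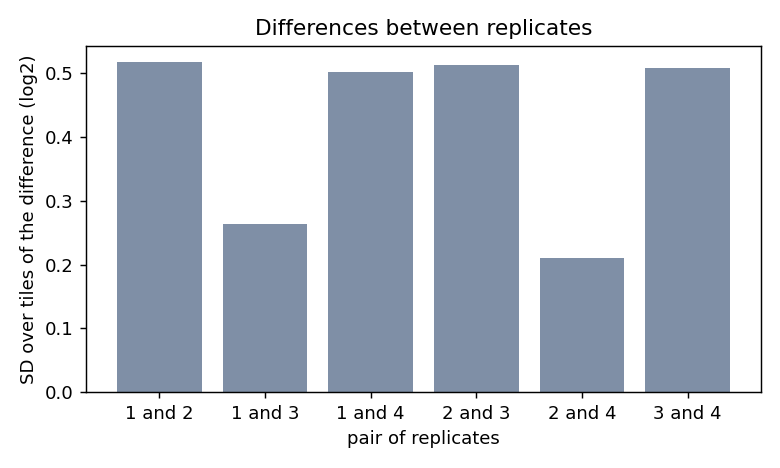
SD over 21285 tiles of the difference in log2 ratio (y axis) for each of the 6 pairs of replicates (x axis). Pairs 1 and 3 and 2 and 4 lie at 0.26 and 0.21, the others between 0.50 and 0.52.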

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

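None of the 18 results with a value per replicate had a replicate that stood apart by Dixon's test. The largest gap was 0.79 of the range, for tile TA37C01, below the critical value for 4 samples. Dixon's test looks for 1 replicate apart from the rest and cannot flag a split of 2 against 2. It therefore does not speak to the split of replicates 1 and 3 from 2 and 4. On TC17 to TC30 these pairs had medians of -2.57 and -2.59 against -1.88 and -1.90, with a gap of only 0.02 of the range.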

How the results depend on the processing

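The replicate pairings other than slide pairs, and all alternatives for plates and wells, were added after the data were seen. The number of tiles above the median tile moved by over 1.5 times in 3 settings: 4108 as deposited, 3592 centred on the mode and 5515 at 1.5-fold or more, against 8951. The number below moved that far in 1, to 13604 centred on the mode, against 8926. Both follow from the construction: mode centring moves the median of all tiles by -0.68 to -0.98, and a size threshold asks for more. Without one replicate, the counts ranged from 8506 to 8653 above and 8534 to 8679 below. The comparison of the slide pairs gave 0 to 8 tiles, with 1 without replicate 3 and 8 without replicate 4, fits in which an arm has 1 sample, assumed to vary like the other arm; the cause was not tested. The 4 named tiles kept their sign and stayed past the threshold in all 14 alternatives, with adjusted p up to 6.01e-05 in limma. Fits with 1 variance for all tiles or a negative block correlation add little here. Their values fell by 0.60 as deposited and by 0.86 centred on the mode, over 1 SD for each, and moved by at most 0.50 SD in the other alternatives. Replicates 1 and 3 against 2 and 4 gave 11830 tiles as deposited and 3928 to 7501 without one replicate, with 3928 without replicate 2 and 4239 without 4; the cause was not tested. Runs had a mean length of 6.08 and at most 84 wells with 1 uncalled tile allowed, and 2.36 and 22 at 1.5-fold, which follows from longer joins and fewer calls. The medians of plate sets and low runs fell with the centring by over 1 SD, and changed sign as deposited and on the mode for TB (-0.11 and -0.36) and the plates that are not low (-0.30 and -0.54), and on the mode for TD (-0.12). The number of low plates rose from 43 to 53 as deposited and to 64 centred on the mode. The 0 low TB plates are given for the median centring only. The remaining counts moved by less than 1.5 times, and the differences between plate sets and the neighbour correlations by less than 1 SD. Dye orientation, a dye effect and 8 blocked arrays were not run because the arrays of a swap are identical, nor were annotation classes, chromosome regions and gene lists. Each ratio already sets IP against input within a replicate, and no further paired analysis was possible because there is 1 group. Signal over background is unknown.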

Other observations

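The tests of whole-plate production and of the longest run were set before their results were seen; the others below, and the patterns themselves, were chosen afterwards. The design names no second group, and no test of a biological explanation is reported.

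Called tiles lay in runs along the wells. The 8951 tiles above the median tile formed 2298 runs of consecutive wells, with a mean length of 3.90 wells. In 1000 shuffles of the tiles within their plates the mean length was 2.13 and never above 2.18, which argues against chance placement. The longest run held 38 wells, from TD01C12 to TD01G01, and 5 of the 1000 shuffles reached that length, a result between the bounds set for this test. The next were TB45E11 to TB45H05 with 31 wells and TC05B06 to TC05D11 with 30. The similarity of neighbours passed from one plate to the next: the correlation of a plate's last well with the next plate's first well was 0.69 in TA and 0.54 in TB, against 0.74 and 0.61 between neighbours within plates. In TC, with 21 such pairs, it was 0.87 against 0.84. Allowing 1 uncalled tile within a run gave 1588 runs with a mean length of 6.08 and a longest of 84 wells. Calls of at least 1.5-fold gave 2332 runs, with 2.36 and 22; neither was set against shuffles.

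The runs of low plates may come from the making of whole plates, from tiles too dim to measure, or from an order of the tiles along the chromosome. At the 4 edges of TA21 to TA30 and TA37 to TA51, the best change point lay 16, 16, 19 and 17 wells from the plate border, in all 4 cases within the neighbouring plate, which argues against a step on whole plates for these 2 runs. Values with 8 or fewer decimals were taken here as a sign that both channels were bright. They were more frequent than on the other plates by 12.9 percentage points on TA37 to TA51 and 19.8 on TC17 to TC30. As far as that inferred sign holds, this argues against these 2 runs being dimmer as a whole than the other plates. Only 28.1% of the values on TA37 to TA51 and 35.0% on TC17 to TC30 carried the sign. The values without it may still come from dim tiles. The size of the difference on TC rests in part on TC17, TC28 and TC29, with 77.5%, 53.6% and 77.9%. Without these 3 plates it was 10.7, between 4.84 and 16.6 in the 4 replicates, and so partly under the 5 points set for this test. On TA37 to TA51 it was 10.9 without the 3 highest plates, TA38, TA43 and TA51. It lay between 4.86 and 17.6 in the 4 replicates there, so also partly under 5 points. On TA21 to TA30 the difference was 1.25 and on TA57 to TA59 -0.23, with both signs among the replicates, so dimness stays open for these runs, and an order of the tiles along chromosome 4 stays open for all, under either direction of the ratio.

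The split of replicates 1 and 3 from 2 and 4 is in neither label that could give a batch. Shared slide numbers would make replicates 1 and 2, and 3 and 4, most alike, but the correlations of 1 and 3 and of 2 and 4 were higher by at least 0.044; a slide effect beside this split stays open. Shared IP chromatin of replicates 2, 3 and 4 would bring replicate 3 closest to 2 and 4. Its correlation with replicate 1 was instead higher by 0.044. The inputs of these replicates carry separate labels, and their part in the split was not tested. An unequal spread of values is not the whole cause, since 7554 tiles passed after quantile normalization; separate chromatin preparations, array batches and exchanged replicate numbers stay open. The difference, replicates 1 and 3 minus 2 and 4, had a median of -0.48 on the low plates and 0.00 on the others, where it went both ways: its median size was 0.52 and 0.27, so the split is not confined to the low plates.

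The lowest tiles alternated between plates at the start of the TA set. Of 173 tiles with a mean below -3.5, 55 lay on TA01 to TA20, and 54 of these were on even-numbered plates, 5.86% of the 922 tiles there against 0.106% of 944 on odd plates. All 10 even plates held such a tile, against 1 of the 10 odd plates. These plates and the limit were chosen because the alternation was seen, so no p is given. Among the 104 lowest tiles on the other TA, TB and TC plates, 33.7% were on even plates, so the alternation did not extend to them. The remaining 14 lay on 1 plate, PD02, within the stretch of wells from PD02F08 to PD02H12. The highest mean in that stretch was -1.33, at PD02G10. The 93 wells beside the lowest tiles on TA01 to TA20 had a median of -1.76, and 18.3% of them were also below -3.5. Plate or spot production of the first plates may be the source, and what the even plates were filled with is as open. On TA01 to TA20 the lowest tiles had a median difference, replicates 1 and 3 minus 2 and 4, of 0.34, and on PD02 of 0.31.

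Exchanging IP and input within replicates gave 8 patterns of sign. The real one called 17877 tiles, 1 pattern of 8 reached that number, and the highest of the others called 0. With 8 patterns a share under 0.05 cannot be reached. Turning the sign of only some replicates moves the signal they share into the error. With replicates as alike as these, 0 calls followed by construction and is no support for the real calls.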
